A study of Rattus norvegicus with 16 samples.

How the data were processed

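The 16 arrays came from 4 rats, 4 arrays in each of 4 groups, per the labels. Per the labels' protocols, about 1000 junctions per muscle and equal non-synaptic regions were laser captured from 10 µm sections stained for acetylcholinesterase. RNA was amplified over a pair of cycles with biotin labelling, and 600 ng of amplified RNA went onto each Affymetrix rat array. The deposited values are linear probe set intensity, scaled by the authors so that the mean without the top and bottom 2% of probe sets is the same on every array. The software that summarised the probes is not given in the sources used here. The number of arrays limits the precision.

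Choices of test, filter, the 26 gene lists and the alternatives were fixed before the data were examined, except a list of ERK targets and the alternative without the 3 arrays of highest median, which were added later. The log2 medians of the arrays differed by 0.563, over the limit of 0.5 set for alignment, so log2(intensity + 16) values were quantile normalized. The 57 control probe sets were left out. Gene names came from the annotation of the array with symbols from the gene table of assembly GRCr8, used for names only: 20832 probe sets had 1 gene, 436 had several, and 9780 were not listed. A probe set was tested if above its array's median in at least 4 arrays, and the probe set with the highest mean stood for its gene, which left 10416 genes.

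Groups were compared with limma 3.58.1 in R 4.3.3, with 4 group means and the rat as a fixed block (residual degrees of freedom 9, prior 4.58), and Benjamini-Hochberg adjustment over all genes in each of 5 contrasts, the interaction being the junction difference in EOM minus that in TA. Of 26 gene lists, 24 with at least 5 measured members were tested with camera at a preset correlation of 0.01, and again with the correlation estimated for each list. The lists of retina and erythrocyte markers had 4 and 3 measured members and were not tested. Each list's count was also adjusted over the list alone. Overlaps were tested with Fisher's exact test, 3' to 5' ratios with exact permutation tests.

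The replicate numbers in the titles were read as animals. After group means were removed, 24 pairs of arrays from the same rat correlated with a mean r of 0.112 (-0.0666 to 0.245, 16 over 0.1), pairs from other rats with -0.0374, and 14 of 16 arrays were closest to their own rat. These values are across genes, which are not independent replicates. The value for other rats is no separate comparison, since removing group means pushes it below 0 when the same-rat value is above 0. The check cannot tell a shared animal from a processing batch shared under the same number.

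Named genes are the 10 with the largest rise and the 10 with the largest fall in each contrast of 2 groups among genes past the threshold with that sign in all 4 rats, 5 and 5 for the interaction, up to 4 members past the threshold of each list described, and a fixed set of receptor, myosin and complement regulator genes. Not all are printed. Musk lay below the filter, Ache had no named probe set, and Cd59 was measured as Cd59b.

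The steps were tested on simulated data with log2 changes of 0.5, 1, 2 and 4. For EOM_fiber against TA_fiber (10451 genes) 4.08, 36, 85.1 and 98% of the changed genes were recovered, and 0.917% of calls were false. For EOM_synapse against TA_synapse (10503 genes) the shares were 0, 50, 72 and 96%, with 7.69% false, and for EOM_synapse against EOM_fiber (10516 genes) 2.04, 45.8, 81.2 and 95.9%, with 5.22% false. For TA_synapse against TA_fiber (10510 genes) they were 4.17, 43.5, 89.8 and 100%, with 5.79% false, and for the interaction (10509 genes) 0, 12.5, 65.3 and 98%, with 6.52% false. The simulated list was called in all 5 contrasts and 0 of 24 random lists were. That list held only genes given a change of 1 or 2 in the same direction, so its call was nearly certain. The simulated noise was independent between probe sets, only a small part of the genes was changed, and the random lists held unchanged genes. Random lists could therefore hardly be called, and these rates may not hold for real arrays with correlated genes and many changes.

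Alternatives covered the rat block (none, random), only the arrays of a contrast, the prior, normalization (as deposited, median centred), filters, pseudocounts of 1 and 64, the choice of probe set, a 2-fold minimum, and leaving out each array and each rat.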

Results

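Messenger RNA was measured in 2 skeletal muscles of 4 rats, the rectus extraocular muscles (EOM), which move the eye, and the tibialis anterior (TA), a limb muscle of the lower leg. From each muscle, regions at the neuromuscular junction and regions of fibre away from it were cut out of frozen sections by laser, after staining for acetylcholinesterase had shown the junctions. Each of the 4 groups (EOM_fiber, EOM_synapse, TA_fiber and TA_synapse) held 4 arrays, 1 from each rat, numbered 15, 25, 27 and 29. Every array gave 31099 probe set intensities, and 10416 named genes passed the filter on low values. Between arrays of a group, the correlation of log2(intensity + 16) lay from 0.867 to 0.949, across all probe sets but the controls and before normalization. The 2% trimmed mean intensity was 150.06 to 150.08 on every array, while the median ran from 33.43 to 57.04. No transcript count stands behind these intensities, so the number of arrays sets the precision. Values below are quantile-normalized log2(intensity + 16), group values are means ± SD with n = 4 arrays, and differences are log2 ± SE. A named gene had the stated direction in all 4 rats unless another number is given. A fold change on this scale understates the change of a dimly measured gene.

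The first comparison asked how the fibres of the 2 muscles differ away from the junction. The 4 myosin heavy chain genes Myh13, Myh8, Myh3 and Myh6 were far higher in EOM fibre, and several Hox genes, which mark position along the body axis, were far lower. Myh13, the extraocular myosin heavy chain, stood at 14.10 ± 0.37 in EOM_fiber and 5.53 ± 0.79 in TA_fiber (difference 8.58 ± 0.33 (SE), adjusted p = 3.48e-09). Myh8, the perinatal myosin heavy chain, differed by 8.29 ± 0.32, Myh3, the embryonic one, by 6.40 ± 0.77, and Myh6, the alpha-cardiac one, by 3.21 ± 0.62 (adjusted p = 3.48e-09, 0.000108 and 0.00325). Of the 11 measured genes of the developmental and extraocular sarcomere list, 5 rose and 1 fell (adjusted over the list alone, 6 and 1), with a camera adjusted p of 0.000241 (adjusted p = 0.0883 with an estimated correlation). The adult fast and slow myosins did not differ past the threshold: Myh4 differed by 0.11 ± 0.17 (2 of 4 rats), Myh1 by 0.05 ± 0.23 (2 of 4), Myh2 by -0.67 ± 0.25 and Myh7 by 0.89 ± 0.42 (3 of 4), with adjusted p = 0.72, 0.912, 0.084 and 0.176. Hoxa9 was at 4.25 ± 0.12 in EOM_fiber and 9.25 ± 0.30 in TA_fiber, a difference of -5.01 ± 0.26 (SE), adjusted p = 5.45e-08. The 9 measured genes of the limb position list were all Hox genes, as its members Pitx1, Tbx4, Tbx5 and Tbx15 were not measured. In that list 7 of the 9 fell and none rose (adjusted over the list alone, also 7), among them Hoxa10 (-4.73), Hoxa5 (-3.78) and Hoxc9 (-2.56). Its camera adjusted p was 2.81e-08 and 0.00989 with an estimated correlation.

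**Figure D1:**
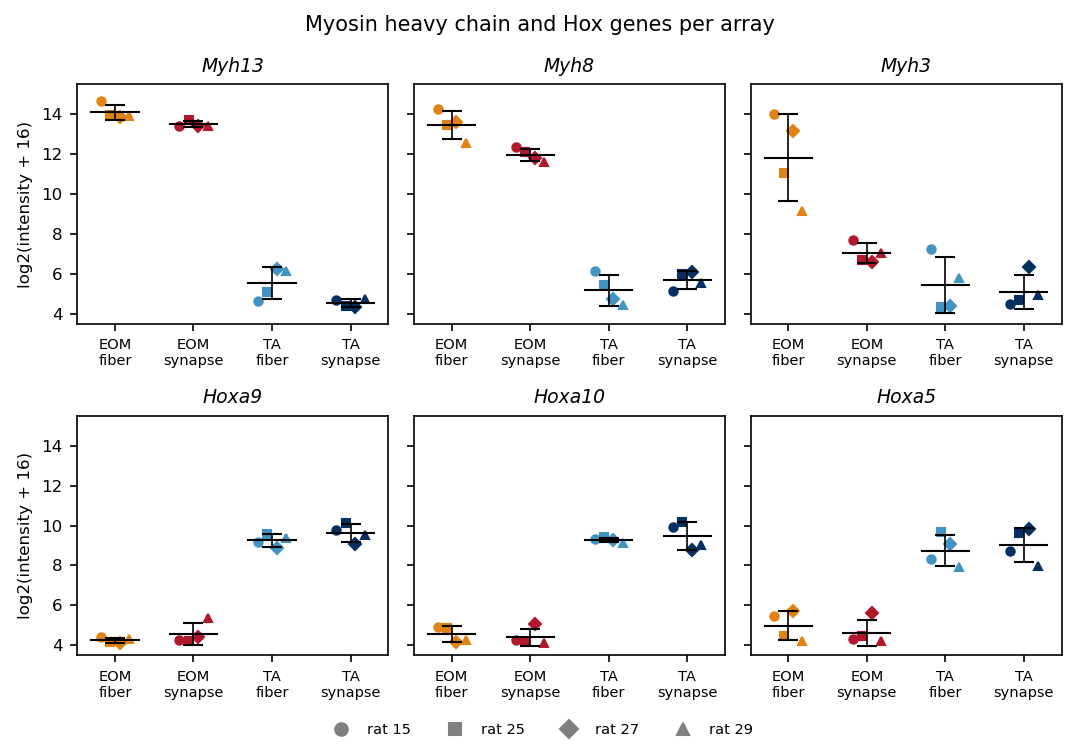
Quantile-normalized log2(intensity + 16) of 3 myosin heavy chain and 3 Hox genes on the y axis, by group on the x axis, each marker 1 array with its shape giving the rat, and the bar and whiskers the mean ± SD (n = 4). Myh13 averages 14.10 and 13.51 in the EOM groups against 5.53 and 4.53 in the TA groups, while Myh3 averages 11.83 in EOM_fiber and 7.02 in EOM_synapse.

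Other genes with the largest differences were Frzb, a secreted Wnt antagonist (7.97 ± 0.32), the small GTPase Rab15 (6.62), Guca1a, a guanylate cyclase activator (5.79), Mybphl (4.97) and the fatty acid desaturase Scd (4.88), all higher in EOM_fiber. The methyltransferase Smyd2 (-4.99 ± 0.43), Rhou (-4.22), Mss51 (-3.92) and the M-band protein gene Myom2 (-3.73) were lower. Small regulators of the sarcoplasmic reticulum calcium pump, Pln (3.18) and Sln (2.85), were higher, although their list did not pass the threshold (6 of 23 higher, 2 lower, camera adjusted p = 0.466).

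Postsynaptic and connective tissue genes were also higher in EOM than in TA fibre. Of 21 measured genes of the acetylcholine receptor and postsynaptic list, 10 rose and 1 fell (adjusted over the list alone, 10 and 1), with a camera adjusted p of 2.84e-05 and 0.00989 with an estimated correlation. The receptor subunit Chrna1 was at 8.96 ± 0.28 in EOM_fiber and 5.43 ± 0.98 in TA_fiber (3.52 ± 0.32 (SE), adjusted p = 1.55e-05) and Chrnd differed by 1.81 ± 0.30. Chrne, the adult subunit, differed by 0.61 ± 0.32 (adjusted p = 0.228, 2 of 4 rats), and Dtna, which encodes alpha-dystrobrevin, was lower (-1.74). Colq, the collagen tail of acetylcholinesterase, was higher by 1.66 ± 0.42 in 3 of 4 rats, a call lost without EOM_fiber 27 (adjusted p = 0.0635). In the fibroblast and extracellular matrix list 13 of 25 genes rose and none fell (adjusted over the list alone, 17 rose), with Lum (2.56), Gsn (2.23), Dcn (1.84) and Pdgfra (1.65) leading. Its camera adjusted p was 3.1e-09 (adjusted p = 0.0883 with an estimated correlation).

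Markers of other cell types moved with the muscle. In EOM_fiber the neuron and axon list had 3 of 6 genes higher, led by the neurofilament gene Nefm (2.73) and Gap43 (1.65), the macrophage and immune list 5 of 16, led by Csf1r (1.996), the endothelial list 3 of 16, led by Aqp1 (1.28), and the complement list 4 of 12, led by Serping1 (2.38). No member of these 4 lists was lower. Adjusted over the list alone, the numbers higher were 3, 6, 3 and 5. On that count, 1 complement gene was lower. Their camera adjusted p was 0.00234, 0.00105, 0.02 and 0.0313, and with an estimated correlation the adjusted p was 0.0883, 0.0985, 0.29 and 0.309. The endothelial call was lost without EOM_fiber 25, or TA_fiber 27 (adjusted p = 0.0601 to 0.0754) and the complement call without EOM_fiber 15, 25 or 27 (adjusted p = 0.0526 to 0.0639). Of 17 neuron and axon genes only 6 passed the filter, and Snap25, Syt1, Chat and Slc18a3 were among those that did not. At the junction against fibre, that list's median was -0.133 in EOM and 0.717 in TA (camera adjusted p = 0.978 and 0.075). The Schwann cell list had 2 of 11 genes higher, Pmp22 (2.19) and Mbp (1.88), and none lower (adjusted over the list alone, 2 higher). Its median was 0.53 (camera adjusted p = 0.0507, adjusted p = 0.488 with an estimated correlation), past the threshold as deposited (0.046) and median centred (0.0213). The membrane complement regulators Cd55 (-0.47 ± 0.33, adjusted p = 0.382, 3 of 4 rats) and Cd59b (0.29 ± 0.18, adjusted p = 0.309) did not differ past the threshold between the fibre groups.

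In all, 1620 of 10416 genes differed between EOM_fiber and TA_fiber (limma, adjusted p under 0.05), 875 higher and 745 lower in EOM, or 54.0% higher. With the arrays centred on a common median the split was 777 higher and 1168 lower (39.9% higher), and with values as deposited the median of all genes shifted by 0.11, so the balance of directions depends on the scaling. Some lists moved with it: the fast fibre list had a median of 0.000199 (camera adjusted p = 0.334), but -0.40 as deposited (0.00118) and -0.57 median centred (0.00119). The oxidative list went from 0.08 (0.84) to -0.17 (0.0236) and -0.34 (0.0113), and the glycogen list from -0.27 (0.0811) to -0.55 (0.000143) and -0.72 (0.000135). Fitting only the 8 arrays of this comparison gave 582 genes, and leaving out all arrays of rat 15 or of rat 27 gave 976 and 982. Without rat 29 the lower count was 465.

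The same question was asked at the junctions. Myh13 (8.98 ± 0.33), Myh8 (6.28), Frzb (6.74), Guca1a (4.48) and Scd (4.36) were again higher in EOM, and Hoxa10 (-5.09), Hoxa9 (-5.07), Mss51 (-4.82) and Smyd2 (-4.68) lower. The limb position list had 6 of 9 genes lower and none higher (adjusted over the list alone, 7 lower), with a camera adjusted p of 6.02e-07 and 0.021 with an estimated correlation. Rcan2, a calcineurin regulator, was at 13.81 ± 0.20 in EOM_synapse and 8.50 ± 0.46 in TA_synapse (5.31 ± 0.28 (SE), adjusted p = 3.75e-08), Fst, which encodes follistatin, differed by 3.99 ± 0.28, and the cell cycle inhibitor Cdkn1a by 3.87 ± 0.45. The carbonic anhydrase Car3 was at 7.93 ± 0.60 against 14.15 ± 0.07 (-6.22 ± 0.28 (SE), adjusted p = 1.5e-08), and Myom2 differed by -7.15 ± 0.32. Calml4 (-5.65), the neuronal pentraxin Nptx1 (-5.25), Gmfg (-5.12) and Klkb1 (-4.45) were likewise lower in EOM_synapse.

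Fast fibre genes were lower at the EOM junction than at the TA junction: 5 of 15 fell and none rose (adjusted over the list alone, 7 fell), with Mybpc2 (-2.49), Myh2 (-2.19) and Actn3 (-2.17), and a camera adjusted p of 0.0023 (adjusted p = 0.23 with an estimated correlation). Glycogen and glycolysis genes had 7 lower and 2 higher of 20 (adjusted over the list alone, 8 and 2), among them Gpd1 (-2.14) and the muscle glycogen phosphorylase Pygm (-0.85, 3 of 4 rats), with Gbe1 higher (2.17). In the oxidative phosphorylation and citrate cycle list 6 of 31 rose (adjusted over the list alone, also 6), led by the coactivator Ppargc1a (1.85). The camera adjusted p was 0.00549 for glycogen and 0.00747 for oxidative genes, and the adjusted p was 0.351 for both with an estimated correlation. The oxidative list lost its call as deposited (median 0.01, adjusted p = 0.5) and median centred (-0.06, adjusted p = 0.619). The developmental and extraocular sarcomere list (5 of 11 higher, 1 lower; adjusted over the list alone, 6 and 1) had a camera adjusted p of 0.00918, and adjusted p = 0.335 with an estimated correlation. Between the junctions the postsynaptic list did not pass the threshold (camera adjusted p = 0.0963), with Chrna1 at 0.63 ± 0.32, Chrnd at 0.74 ± 0.30 and Chrne at 0.94 ± 0.32 (adjusted p = 0.203, 0.106 and 0.0624). Cd55 was higher at the EOM than at the TA junction (1.27 ± 0.33 (SE), adjusted p = 0.0175), a call lost without EOM_synapse 15 or 27, or TA_synapse 27 (adjusted p = 0.0569 to 0.0649). Against fibre of the same muscle, Cd55 did not pass the threshold at the EOM junction. In the fit over all 4 rats it was lower at the TA junction than in TA fibre. That call was lost without TA_fiber 15, 25 or 27, or TA_synapse 25, 27 or 29 (adjusted p = 0.0607 to 0.123). The call of Pygm was lost without EOM_synapse 15, 25 or 29, or TA_synapse 15, 25 or 29 (adjusted p = 0.054 to 0.0934). Schwann cell markers were higher too, with 2 of 11 genes past the threshold (adjusted over the list alone, also 2), Mbp (1.62) and Pmp22 (1.24). The list's camera adjusted p was 0.00735, and adjusted p = 0.351 with an estimated correlation.

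Between EOM_synapse and TA_synapse 1712 genes differed, 815 higher and 897 lower in EOM, or 47.6% higher. As deposited the split was 935 higher and 834 lower (52.9% higher) and with the arrays centred on a common median 747 and 1007 (42.6% higher), so the majority direction depends on the scaling. Without rat 25, 27 or 29 the number was 1135, 996 and 947, and without EOM_synapse 25 the higher count was 539. The muscle difference was shared between regions: across genes, the log2 differences correlated with Pearson's r = 0.636 and Spearman's rho = 0.574, genes not being independent replicates. Past the threshold in both regions, 397 genes were higher and 438 lower in EOM, where independent lists would share 68.5 and 64.2, and 5 were opposite (Fisher's exact p = 1.33e-236 and 2.81e-308). These p-values also take genes as independent and do not measure how well the overlap repeats across rats.

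Within EOM, the junction was compared with the fibre of the same muscle to find synaptic genes. Chrne was at 11.36 ± 0.14 at the junction and 4.995 ± 0.83 in fibre (6.36 ± 0.32 (SE), adjusted p = 1.07e-07). The transcription factor gene Etv5 differed by 5.42 ± 0.36, Chrna1 by 3.85 ± 0.32 and the adhesion molecule Ncam1 by 3.60 ± 0.26. Of 21 measured postsynaptic genes 14 rose and none fell (adjusted over the list alone, 14 and 1), with a camera adjusted p of 2.63e-11 and 0.000833 with an estimated correlation. Rapsn, which clusters the receptor, did not rise on these arrays (-0.36 ± 0.25, adjusted p = 0.402, lower in 3 of 4 rats). Also among the largest differences were the atrial and embryonic light chain Myl4 (5.85), the transcription factor gene Pou3f1 (4.74), Hs6st2, a heparan sulphate sulphotransferase (4.52), Col19a1 (4.42), Postn (4.40), the kinase Map2k1 (4.31) and Dusp6, a phosphatase of ERK (4.12).

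**Figure D2:**
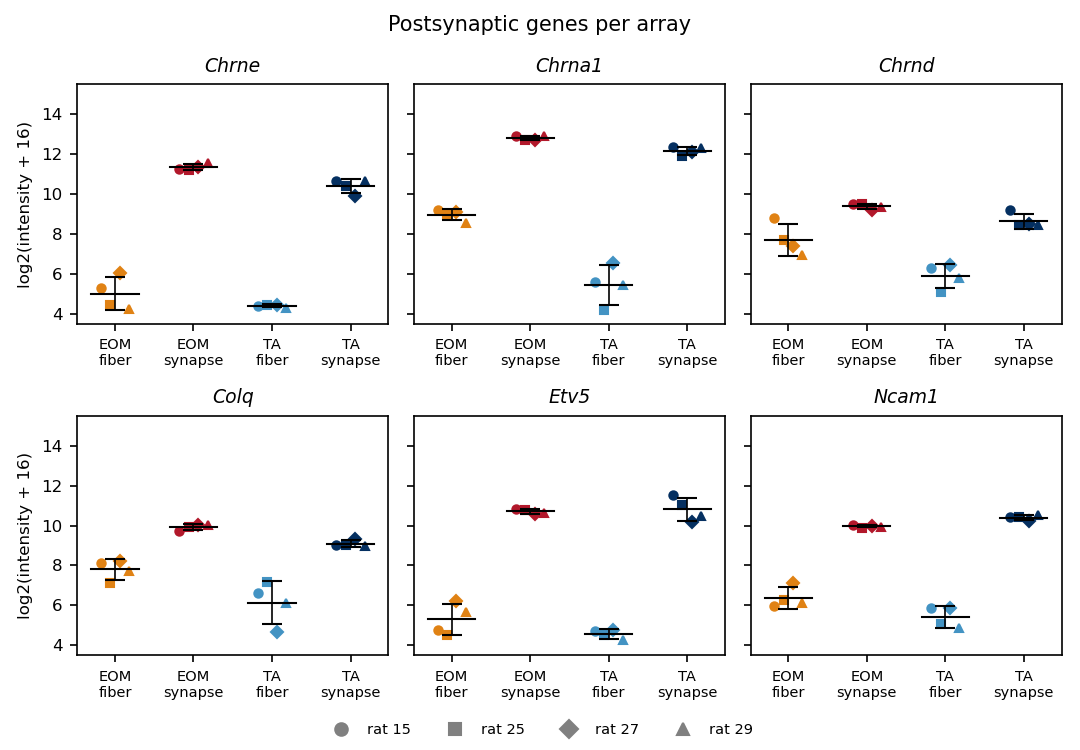
Quantile-normalized log2(intensity + 16) of 6 genes of the postsynaptic list on the y axis, by group on the x axis, each marker 1 array with its shape giving the rat, and the bar and whiskers the mean ± SD (n = 4). Chrne averages 4.995 and 4.39 in the fibre groups against 11.36 and 10.42 at the junctions, while Chrna1 averages 8.96 in EOM_fiber and 5.43 in TA_fiber.

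Schwann cell genes rose at the EOM junction in 7 of 11 cases with none lower (adjusted over the list alone, 10 rose), S100b by 2.90 ± 0.32, Mbp by 2.83 ± 0.36 and Prx by 2.60 ± 0.57, and the camera adjusted p was 6.06e-09 and 0.0425 with an estimated correlation. Fibroblast and matrix genes rose in 8 of 25 (adjusted over the list alone, 11), Lum by 1.85 and Pdgfra by 1.43 (camera adjusted p = 5.07e-05; adjusted p = 0.16 with an estimated correlation). Endothelial genes fell in 6 of 16 (adjusted over the list alone, 8), with Aqp1 at -1.22 and Vwf at -1.10. Smooth muscle and pericyte genes fell in 5 of 13 (adjusted over the list alone, also 5), with Mcam higher (1.43). Macrophage and immune genes fell as a list (camera adjusted p = 0.0338), with Mrc1 past the threshold (-1.04) among all genes and 0 adjusted over the list alone. The camera adjusted p was 0.000215 for endothelial and 0.0109 for smooth muscle genes, and with an estimated correlation the adjusted p of these 3 lists was 0.0973, 0.149 and 0.252. Calls were lost for the macrophage list without EOM_fiber 27, or EOM_synapse 15 or 29 (adjusted p = 0.055 to 0.139), for Mrc1 without EOM_fiber 25, 27 or 29, or EOM_synapse 15, 25, 27 or 29 (adjusted p = 0.0601 to 0.12) and for Vwf without EOM_fiber 25, 27 or 29, or EOM_synapse 15, 25 or 29 (adjusted p = 0.0577 to 0.129).

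Contractile and metabolic genes were lower at the EOM junction. Myh3 was at 7.02 ± 0.50 there and 11.83 ± 2.18 in fibre (-4.81 ± 0.77 (SE), adjusted p = 0.00133), Myh8 differed by -1.50 ± 0.32, and Myh13 by -0.60 ± 0.33 (adjusted p = 0.281). In the slow fibre list 9 of 14 genes fell and none rose (adjusted over the list alone, 11 and 1), with Myl3 (-2.35), Myl2 (-2.33), Tnni1 (-2.31) and Myh7 (-1.84, a call lost without EOM_synapse 15 (adjusted p = 0.0593)). In the fast fibre list 6 of 15 fell (adjusted over the list alone, 9), with Myh2 (-2.22), Mybpc2 (-1.33) and Casq1 (-1.32). Glycogen and glycolysis genes fell in 7 of 20, excitation-contraction coupling genes in 8 of 23 with 2 higher, fatty acid genes in 6 of 20 and oxidative genes in 3 of 31 (adjusted over the list alone, 10, 10, 7 and 3). The camera adjusted p was 3.8e-07 for slow, 8.3e-06 for fast, 3.06e-06 for glycogen, 0.0129 for coupling, 0.000919 for fatty acid and 0.00967 for oxidative genes. With an estimated correlation only the fast list kept its call among these 6 (adjusted p = 0.0425), and the others had an adjusted p of 0.134, 0.125, 0.0842, 0.239 and 0.325. Among single genes, Car3 (-4.50 ± 0.28), Myom2 (-3.33 ± 0.32) and the water channel Aqp4 (-2.94 ± 0.39) fell most after Myh3.

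Between EOM_synapse and EOM_fiber 1055 genes differed, 585 higher and 470 lower at the junction. Leaving out all arrays of rat 15, 25, 27 or 29 gave 491, 657, 614 and 544 genes, and leaving out the junction array of rat 15 or of rat 29 gave 630 and 649. The lower count of 470 fell to 227, 291, 292 and 250 without EOM_synapse 15, 25, 27 or 29, and to 307 and 280 without EOM_fiber 15 or 25, and to 163 to 231 without 1 rat.

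Within TA the same question was asked, and the largest rises at the junction were those of Nptx1, at 11.17 ± 1.96 against 4.39 ± 0.30 in fibre (6.77 ± 0.67 (SE), adjusted p = 1.63e-05), and Chrna1, at 12.18 ± 0.20 against 5.43 ± 0.98 (6.75 ± 0.32 (SE), adjusted p = 2.19e-08). Postn (6.58), Etv5 (6.26), Map3k7cl (6.16), Myl4 (6.12), Chrne (6.03), Calml4 (5.67), the endothelial protein gene Plvap (5.65) and Dusp6 (5.50) followed. The postsynaptic list had 14 of 21 genes higher and none lower (adjusted over the list alone, 16 and 1), Ncam1 by 4.98 ± 0.26, Colq by 2.95 ± 0.42 and Chrnd by 2.75 ± 0.30, with a camera adjusted p of 6.99e-15 and 0.000273 with an estimated correlation. Rapsn differed by -0.26 ± 0.25 (adjusted p = 0.588, 2 of 4 rats).

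Connective tissue and Schwann cell genes rose at the TA junction. Of 25 fibroblast and matrix genes 13 rose (adjusted over the list alone, 18 rose and 2 fell), Lum by 3.55 ± 0.29, Col6a3 by 2.95 ± 0.30 and Pdgfra by 2.72 ± 0.22. Of 11 Schwann cell genes 6 rose (adjusted over the list alone, 7), Mbp by 3.09, Pmp22 by 3.04 and S100b by 2.50. The basement membrane genes Lama2 (3.56) and Lama4 (1.97) led 4 of 14 sarcolemma genes that rose (adjusted over the list alone, 5 and 1 fell). The camera adjusted p was 2.91e-13, 3.95e-07 and 0.0286 for these lists, and with an estimated correlation the adjusted p was 0.0539, 0.0747 and 0.28. The sarcolemma call was lost without TA_synapse 29 (adjusted p = 0.114), as deposited (adjusted p = 0.0756) and median centred (0.0777). Endothelial genes fell in 5 of 16 (adjusted over the list alone, 6), with Sox17 at -1.19, a call lost without TA_fiber 25, 27 or 29, or TA_synapse 25 or 27 (adjusted p = 0.0524 to 0.0891). The list had a camera adjusted p of 0.00106 and an adjusted p = 0.128 with an estimated correlation.

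Slow fibre and oxidative genes were lower at the TA junction, while the call of the fast fibre list depended on the scaling. Slow fibre genes fell in 8 of 14 (adjusted over the list alone, 10), among them Ankrd2 (-2.03), Myl3 (-1.96) and, with calls lost without 1 array, Csrp3 (-1.82, without TA_fiber 15, or TA_synapse 29 (adjusted p = 0.0699 to 0.073)) and Myl2 (-1.79, without TA_fiber 15 or 29, or TA_synapse 25 or 29 (adjusted p = 0.0518 to 0.08)). Myh7 differed by -1.05 ± 0.42 (adjusted p = 0.143, 3 of 4 rats). Oxidative genes fell in 9 of 31 and fatty acid genes in 8 of 20, with 1 fatty acid gene higher (adjusted over the list alone, 15 and 16 fell), among them Ppargc1a (-1.32), the fatty acid binding protein gene Fabp3 (-1.59) and the lipoprotein lipase gene Lpl (-1.42). Glycogen and glycolysis genes fell in 2 of 20 (adjusted over the list alone, 4), a list call lost without TA_synapse 27 (adjusted p = 0.0527). The camera adjusted p was 1.42e-06 for slow, 5.79e-09 for oxidative, 3.95e-07 for fatty acid and 0.00305 for glycogen genes, and with an estimated correlation the adjusted p was 0.175, 0.0747, 0.109 and 0.312. The fast fibre list had 1 of 15 lower, Myh1 (-0.997, a call lost without TA_fiber 27 or 29, or TA_synapse 29 (adjusted p = 0.0501 to 0.0516)). Its median was 0.01 (camera adjusted p = 0.666), but -0.39 as deposited (adjusted p = 0.000114) and -0.51 median centred (adjusted p = 0.000108). Aqp4 fell most of all genes (-3.33 ± 0.39).

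Between TA_synapse and TA_fiber 1066 genes differed, 698 higher and 368 lower at the junction, or 65.5% higher. With the arrays centred on a common median the split was 645 higher and 702 lower (47.9% higher). Fitting only the 8 TA arrays gave 606 genes, and leaving out all arrays of rat 15, 25, 27 or 29 gave 683, 660, 602 and 622. The lower count of 368 fell to 240, 179 and 202 without TA_fiber 15, 27 or 29, to 227 and 190 without TA_synapse 15 or 25, and to 183, 189, 128 and 131 without each rat in that order.

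**Figure D3:**
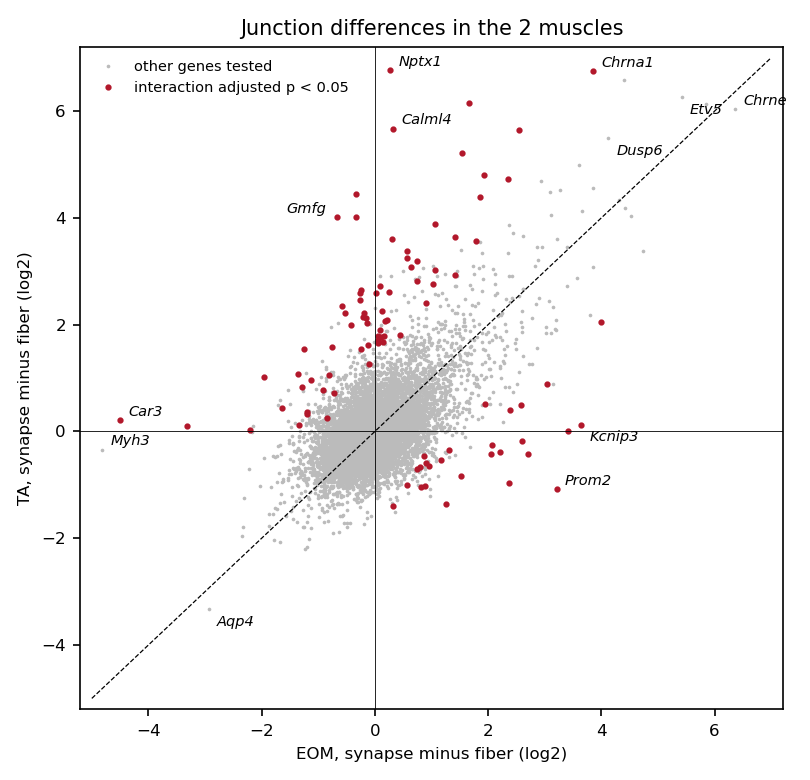
Log2 difference between junction and fibre in EOM (x axis) and in TA (y axis), 1 point per gene for 10416 genes, with the line of equal difference dashed. The 96 genes with an interaction past the threshold are in red, and across genes Pearson's r is 0.58.

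The junction differences of the 2 muscles were then set against each other. Across genes they correlated with r = 0.58 and rho = 0.476. Past the threshold in both muscles, 331 genes were higher and 126 lower at the junction, where independent lists would share 39.2 and 16.6, and 7 were opposite (Fisher's exact p = 7.9e-260 and 3.26e-80). Genes are not independent replicates, so these p-values do not measure how well the overlap repeats across rats. The difference of the differences passed the threshold for 96 genes, 27 with a higher junction-minus-fibre difference in EOM and 69 with a lower one. Of these 69, 57 were raised at the TA junction and 14 were lower at the EOM junction. Prom2 was at 9.74 ± 0.32 in EOM_synapse and 5.55 ± 0.47 in TA_synapse, with 6.53 ± 0.54 and 6.63 ± 0.18 in the fibre groups (interaction 4.29 ± 0.29 (SE), adjusted p = 8.58e-06). Kcnip3 (3.51 ± 0.65), the exchanger gene Slc24a2 (3.41 ± 0.61), Septin6 (3.34 ± 0.57) and Fgf12 (3.11 ± 0.52) followed. Nptx1 was at 5.91 ± 0.32 in EOM_synapse and 5.64 ± 0.54 in EOM_fiber, far from its rise in TA (interaction -6.50 ± 0.94 (SE), adjusted p = 0.00478). Calml4 (-5.34 ± 0.55), the calcium channel subunit gene Cacna2d3 (-4.78 ± 0.36), Car3 (-4.72 ± 0.39) and Gmfg (-4.69 ± 0.36) also had a lower junction-minus-fibre difference in EOM, Car3 by a fall at the EOM junction. Among postsynaptic genes this difference was lower in EOM for Chrna1 (-2.89 ± 0.45 (SE), adjusted p = 0.00698) and Lrp4 (-1.75 ± 0.31 (SE), adjusted p = 0.0175). Both were higher in EOM_fiber than in TA_fiber. Chrne had 0.33 ± 0.45 (adjusted p = 0.858, 2 of 4 rats). The mean fibre values of Chrne in both muscles and of Chrna1 in TA lay below the array medians, so the floor limits these differences. The calls were lost for Lrp4 without EOM_synapse 29, or TA_synapse 15 or 29 (adjusted p = 0.0508 to 0.0519), for Slc24a2 without EOM_synapse 27 (adjusted p = 0.0562) and for Kcnip3 without EOM_fiber 25, or EOM_synapse 15, 25 or 27, or TA_synapse 15 (adjusted p = 0.0503 to 0.0584).

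As lists, matrix genes (median -0.77), fast fibre genes (-0.45), coupling genes (-0.48), immune markers (-0.52) and postsynaptic genes (-0.39) had a lower interaction, and oxidative genes a higher one (0.28). Members past the threshold were 1 of 25 matrix genes, Col1a1 (-1.60), 1 of 15 fast fibre genes, Mybpc2 (-1.45), 2 of 21 postsynaptic genes, and none of the other 3 lists (adjusted over the list alone, 7, 6 and 4, with 4 coupling, 4 immune and 0 oxidative genes). The camera adjusted p was 1.58e-06, 0.000147, 0.00384, 0.00384, 0.00428 and 0.00203 in the order named, and with an estimated correlation the adjusted p was 0.156, 0.0695, 0.0695, 0.178, 0.0695 and 0.33. The call of Mybpc2 was lost without EOM_fiber 25 or 27, or TA_fiber 15, 25 or 29, or EOM_synapse 15, 25 or 27, or TA_synapse 15, 25 or 29 (adjusted p = 0.0507 to 0.0756). The Schwann cell list did not pass the threshold (0.25, camera adjusted p = 0.578). The count of 96 genes was 41 from 1 difference of differences per rat, and 23 to 47 without 1 rat. It moved to 56 or 59 without EOM_synapse of rat 27 or 29, and to 59 or 57 without TA_synapse of rat 15 or 29. Those 4 arrays moved the higher count of 27 to 11, 14, 15 and 14 and the lower count of 69 to 45, 45, 44 and 43. The higher count was also 17 without EOM_fiber 27 or TA_fiber 15, 15 without TA_fiber 27 and 14 without EOM_synapse 15, and the lower count 45 without EOM_fiber 25.

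**Figure D4:**
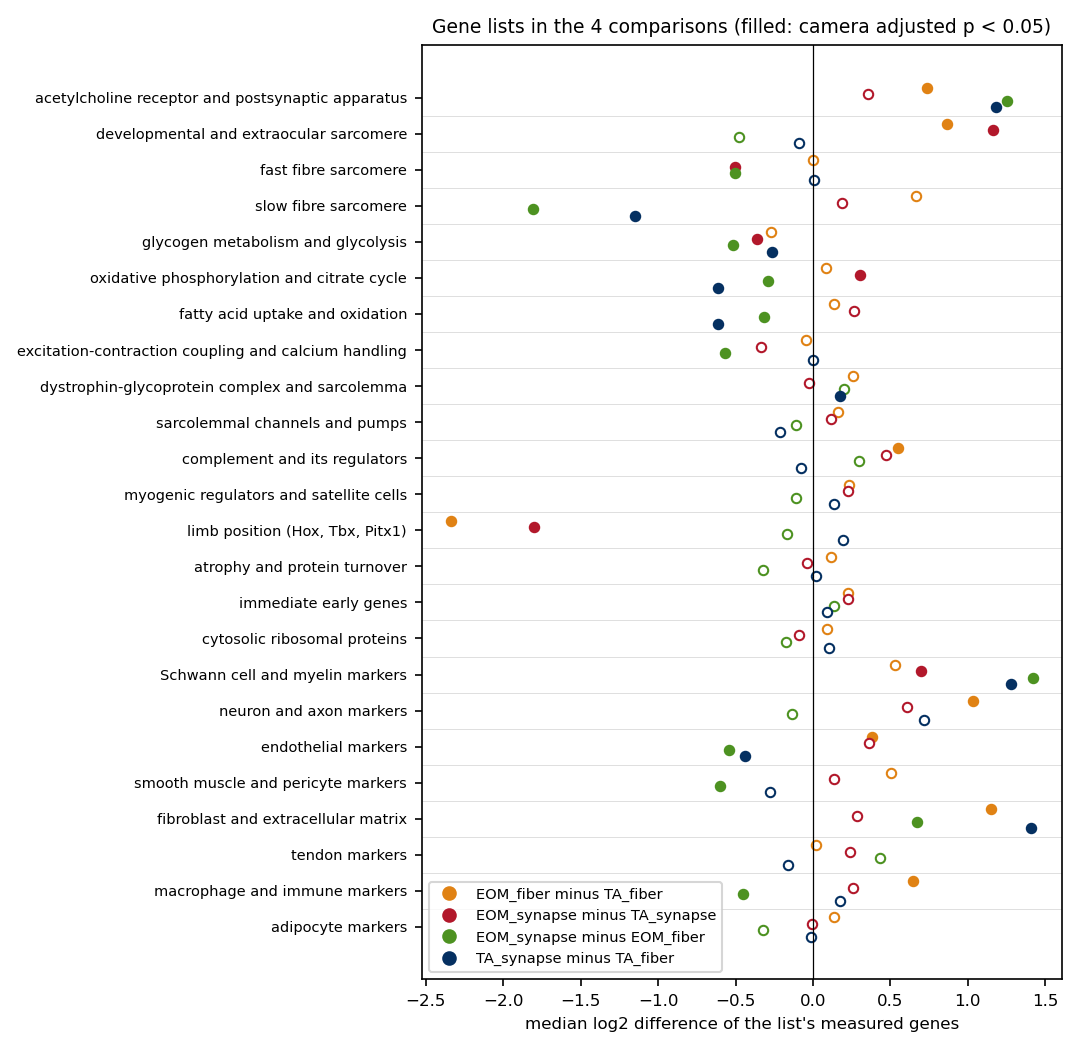
Median log2 difference of the measured genes of each of 24 lists (x axis) in 4 comparisons, given by colour, with filled markers where the camera adjusted p was under 0.05. The postsynaptic list has medians of 1.25 and 1.18 at the EOM and TA junctions, and the limb position list of -2.34 and -1.80 in EOM against TA.

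The 3' to 5' ratios, a measure of RNA quality, were compared with too few arrays for any single one to pass. The log2 ratio of 3' to 5' probe sets for GAPDH was 3.62 ± 0.19 in EOM_fiber, 3.69 ± 0.27 in TA_fiber, 3.35 ± 0.23 in EOM_synapse and 3.60 ± 0.53 in TA_synapse, and for beta-actin 3.21 ± 0.25, 4.19 ± 0.64, 3.57 ± 0.98 and 4.21 ± 0.37 (SD, n = 4). Over 8 comparisons the smallest two-sided exact permutation p was 0.0571 (adjusted p = 0.456), for beta-actin in EOM_fiber against TA_fiber, a difference of -0.98, while the smallest p that 70 splits allow is 0.0286, or 0.229 adjusted if reached once. Within rats the GAPDH ratio was lower in EOM_synapse than in EOM_fiber in 4 of 4 (mean -0.28, SD 0.0591), and the beta-actin ratio lower in EOM_fiber than in TA_fiber in 4 of 4 (mean -0.98, SD 0.747), where 4 pairs allow no p under 0.125. The arrays EOM_fiber 15, TA_fiber 25 and TA_synapse 27 stood apart, with median intensities of 57.04, 51.51 and 53.20 and largest intensities of 94072, 94903 and 79929.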

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

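All tests of causes in this part were chosen after the results were seen, except the counts over other splits of the arrays, which were written before.

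In 25 of 404 groups of 4 arrays, 1 array stood apart, its gap to the nearest other array filling most of the group's range. Chance does this in about 1 in 20 groups. The gap as a share of the range is given in parentheses. In TA_synapse it was Ankrd2 in rat 27 (0.855), Ccnd1 in rat 25 (0.897), Chrnd in rat 15 (0.926), Map3k7cl in rat 25 (0.924), Ppargc1a in rat 27 (0.959) and Pygm in rat 27 (0.984). In EOM_synapse it was Aqp4 in rat 29 (0.83), Csrp3 in rat 25 (0.888), Hoxa10 in rat 27 (0.869), Myh13 in rat 25 (0.969) and Rapsn in rat 25 (0.831). In EOM_fiber it was Casq1 in rat 27 (0.939), Dcn in rat 15 (0.836), Dusp6 in rat 27 (0.903), Klkb1 in rat 29 (0.87), Myh13 in rat 15 (0.899), Myh4 in rat 25 (0.83), Myl3 in rat 27 (0.873) and Prx in rat 29 (0.83). In TA_fiber it was Ccnd1 in rat 25 (0.958), Etv4 in rat 15 (0.95), Guca1a in rat 29 (0.877), Mbp in rat 15 (0.868) and Plvap in rat 27 (0.924). The beta-actin 3' to 5' ratio in EOM_fiber stood apart in rat 25 (0.925).

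The junction difference differed between the muscles, by the test of the interaction, for these named genes. Junction minus fibre was higher in EOM for Fgf12 (3.11), Fst (2.00), Kcnip3 (3.51), Prom2 (4.29), Rcan2 (2.60), Septin6 (3.34) and Slc24a2 (3.41) (log2 interaction). It was lower in EOM for Cacna2d3 (-4.78), Calml4 (-5.34), Car3 (-4.72), Chrna1 (-2.89), Col1a1 (-1.60), Etv4 (-2.88), Gmfg (-4.69), Gpd1 (-1.53), Klkb1 (-4.35), Lama2 (-1.78), Lrp4 (-1.75), Map3k7cl (-4.49), Mybpc2 (-1.45), Myom2 (-3.42), Nptx1 (-6.50), Plvap (-3.10) and Rab15 (-2.80), of which Car3, Myom2, Mybpc2 and Gpd1 were lower at the EOM junction than in EOM fibre past the threshold. Calls were lost for Fst without EOM_fiber 27, or TA_fiber 15, 25, 27 or 29, or EOM_synapse 15, 25 or 27, or TA_synapse 15 or 29 (adjusted p = 0.0534 to 0.0837), for Gpd1 without TA_synapse 15 or 29 (adjusted p = 0.0508 to 0.0516) and for Lama2 without EOM_fiber 15, 25 or 27, or TA_fiber 15 or 27, or EOM_synapse 15, 25, 27 or 29, or TA_synapse 15, 25 or 29 (adjusted p = 0.0523 to 0.103). Among the 5079 probe sets with no gene name or several that passed the filter, which the comparisons leave out, 85 were higher at both junctions, and the 2 with the largest rises at both differed at the EOM junction by 5.31 and 4.39 (log2).

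Postsynaptic genes were higher in EOM_fiber than in TA_fiber, and scaling did not account for it, since the list stayed higher as deposited and median centred (the larger camera adjusted p was 0.000107). Whether junction material in the EOM fibre captures accounts for part of it could not be decided. The share of junction RNA that each gene would need had a median of 11.5% for 13 list members and 13.4% for 318 other genes raised at both junctions (difference -1.92, SD 7.43). This match is no support, because the rats' differences went both ways (-11.5 to 4.13) and the other genes may themselves differ between the muscles. In any rat Chrne needed at most 1.64% and Etv5 at most 3.07%. As the whole cause, junction material would need 1 share for all members, but the mean shares ran from 0.59% for Chrne, 1.3% for Etv5 and 6.38% for Chrna1 to 27.4% for Chrnd, 39.8% for Chrnb1 and 42.1% for Lrp4. The shares differed between members (Friedman test, the largest p over 2 scalings, with and without Dtna, 0.00453), if intensity follows RNA amount linearly. That was the third form of the test: 6 of 13 members lay above a limit from 14 other genes (2.14% on average) in all 4 rats, 1 of them Dtna, whose share has no meaning, and a gap of at least 9.16% between 3 and 2 members picked by their shares decides nothing. Carry-over in part and a difference between the muscles stay open.

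Slow fibre genes were lower at both junctions, and RNA of other cells in the junction captures would lower slow and fast fibre genes alike. In EOM the slow list fell more than the fast list by a median difference of -1.07 (SD 0.176), or -0.745 (SD 0.186) as deposited. With only the 5 fast genes no brighter than the brightest slow gene it was -0.815 (SD 0.169), or -0.625 (SD 0.13) as deposited. That limit does not match the 2 lists in brightness. These values argue against dilution as the whole cause only if bright and dim genes follow RNA amount alike. In TA the difference was -1.24 (SD 0.54), but -0.83 (SD 0.605) as deposited. With only the 4 fast genes no brighter than the brightest slow gene it was -1.23 (SD 0.549), or -0.955 (SD 0.558) as deposited. The difference was below 0 in 4 of 4 rats each time. For TA, dilution and a change in slow fibre genes were not told apart. As deposited the difference lay within the limit set for this test, 2 SD of the 4 rats. That limit is the spread between rats and not the error of the mean. A difference in fibre type at the captured sites was not tested.

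For 69 genes junction minus fibre was lower in EOM than in TA. Junction material in EOM_fiber would place that between the fibre arrays, yet a median of 80.8% of it lay between the junction arrays (quartiles 23.6 and 102%). For the 54 of them raised at the TA junction and not lower at the EOM junction the median was 79.4% (21.2 and 96.8%), so carry-over may bear on part of these genes only. For the 14 called lower at the EOM junction, the median junction change was -1.31 in EOM and 0.396 in TA. Carry-over would shrink an EOM difference without turning it into a fall, so these values argue against it for those 14 genes. More connective tissue in the TA junction captures would raise matrix genes there. The list's median in EOM_synapse minus TA_synapse was 0.274 (SD 0.193, 0.124 to 0.557), above 0 in 4 of 4 rats though within 2 SD. That comparison decides nothing, because the list was already higher in EOM_fiber than in TA_fiber (median 1.15). Within each muscle the list rose at the junction, by a median of 1.41 in TA and 0.669 in EOM. For the other genes as a set, carry-over and a difference between the muscles cannot be told apart, because the quartiles span both outcomes. The median junction change of the 54 genes was 0.157 in EOM and 2.6 in TA. For 47 of the 69 genes the larger part of the difference lay between the junction arrays, which carry-over in EOM_fiber would leave unchanged. Carry-over could be only the smaller part for those 47. Connective tissue stays open for all 69, because matrix genes already differed between the fibre groups.

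Of the 35 splits of each comparison's 8 values, fitted without the rat block, 1, the real one, gave as many genes. The real and the highest other counts were 796 and 1 for the fibre comparison of the muscles, 1686 and 3 for their junctions, 824 and 1 for the EOM junction, 547 and 3 for the TA junction, and 64 and 0 for the interaction. Since the arrays are paired by rat, only the 8 splits that part all 4 pairs compare with the real one, and 8 are too few for a share under 0.05, which the limit written before did not allow for. The highest other of these 8 gave 0 genes, while the other splits leave some rats' pairs together.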

How the results depend on the processing

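The test without the 3 arrays of highest median (EOM_fiber 15, TA_fiber 25 and TA_synapse 27) was chosen after the data were seen, and gave 1197, 1708, 943, 900 and 77 genes in the 5 contrasts (EOM against TA in fibre and at the junction, the EOM and TA junctions, the interaction). Without the rat block the counts were 1383, 1474, 831, 903 and 73, and 15 of 249 gene results lost their call. With the rat as a random block they were 1609, 1685, 1009, 1055 and 103, and camera was not run with it. Only the arrays of the contrast gave 582 genes in fibre, 606 at the TA junction, and shared calls of 266 (junctions) and 394 (muscles), with fewer arrays in the fit. The interaction had 41 from 1 difference of differences per rat, with fewer values in the fit (the cause was not tested). A 2-fold minimum, stricter by construction, gave 943, 931, 648 and 706 genes and shared calls of 285 and 417. The interaction moved to 205 genes with a trend and robust prior, 189 with the 75th percentile filter, 46 with a pseudocount of 1 and 218 with 64 (the cause was not tested). Lists past the threshold fell from 8 to 5 in fibre with the 75th percentile filter, which leaves fewer genes. With an estimated correlation they fell from 8, 6, 12, 9 and 6 to 2, 1, 3, 1 and 0. The oxidative list in EOM_fiber minus TA_fiber, not past the threshold at 0.0827, reversed to -0.174 as deposited and -0.343 median centred (the cause was not tested).

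Without 1 rat the counts ran 976 to 1197, 947 to 1225, 491 to 657, 602 to 683 and 23 to 47, and shared calls 213 to 268 (junctions) and 453 to 541 (muscles), with fewer arrays. Without 1 array they ran 1185 to 1444, 1146 to 1386, 630 to 951, 715 to 929 and 56 to 105, and shared calls 328 to 422 and 636 to 827. The arrays that moved a total over 1.5 times were EOM_synapse 15 (630) and 29 (649) for the EOM junction, and EOM_synapse 27 (56) and 29 (59) and TA_synapse 15 (59) and 29 (57) for the interaction. Over all alternatives, 249 gene results gave 5798 values on the same side of the threshold, 355 weaker, 57 stronger and 0 reversed, and 120 list results 2892, 62, 78 and 2. By construction, the pseudocount of 16 narrows the fold changes of genes with intensities near it.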

Other observations

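All tests in this part were chosen after the junction results were seen. Targets of ERK, a kinase that acts below receptor tyrosine kinases, were higher at both junctions. Of 7 measured genes of a list of 10, 6 rose in each muscle, with a median of 1.97 in EOM (camera adjusted p = 1.91e-08, adjusted p = 0.0106 with an estimated correlation) and 2.51 in TA (1.61e-10, adjusted p = 0.00471 with an estimated correlation). Dusp6 differed by 4.12 and 5.50 (SE 0.255), Etv4 by 1.92 and 4.81 (SE 0.247), Spry2 by 1.97 and 1.83 (SE 0.259), Ccnd1 by 2.41 and 2.51 (SE 0.5) and Spry4 by 1.07 and 1.93 (SE 0.253), while Epha4 did not pass the threshold (-0.30 and -0.29, SE 0.297). The call of Spry4 in EOM was lost without EOM_synapse 25 (adjusted p = 0.0648). Etv5 is on this list and on the postsynaptic list. The list's interaction was lower (adjusted p = 0.00514, adjusted p = 0.141 with an estimated correlation), with Etv4 past the threshold (-2.88). The list was written after rises of its members had been seen, so it is no support for higher ERK output. Its 5 members not among the genes named for the junctions gave a larger camera adjusted p of 0.00024 (0.0332 with an estimated correlation), but the list was still chosen after the tables were seen. RNA of Schwann cells or fibroblasts in the captures was not set against it.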
